A study of Mus musculus with 6 samples.

How the data were processed

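Total RNA of snap-frozen mouse liver was sequenced in 6 libraries, 1 per mouse, with 3 mice labelled WT and 3 labelled AKAP12KO that were matched for age and weight per the series' design text. Per the labels' protocols, RNA was extracted with Trizol and libraries followed standard Illumina procedures, and strand, read layout and batch are not given in the sources used here. The deposited values are raw read counts per gene symbol, 24421 symbols in each of the 6 tables. Per the submitters' processing notes, STAR 2.5.2b, featureCounts and Subread 1.5.1 were used with the mouse build mm10. The gene annotation and the treatment of reads that map to several places or overlap several genes are not given in the sources used here, so counts of near-identical or overlapping genes, such as the Mup and Cyp4a12 families and the globins, are uncertain, and so are counts of genes with antisense partners. No symbol in the tables carries the mt- prefix of mitochondrially encoded genes, and other names for them were not searched. Each table held 1 column of 1 mouse, and 0 columns of other samples were present.

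Groups and replicate numbers were taken from the sample titles. Libraries were compared by the chi-square of their counts over genes, and no pair agreed within sampling noise, so all 6 count as separate mice. The totals per library ran from 11680792 to 13134603 counts. Of the 24421 genes, 7483 had 0 counts in all libraries, and edgeR's filterByExpr left 12220 genes for testing.

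The main test was edgeR 4.0.16 in R 4.3.3: TMM factors, glmQLFit with robust dispersion estimation and glmQLFTest of AKAP12KO against WT with genotype as the only term, over all 6 libraries. Adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. CPM were computed from the deposited counts with TMM-scaled library sizes of the tested genes, and are given as mean ± SD of 3 mice in the order WT, AKAP12KO where a pair is printed. Log2 fold changes are AKAP12KO minus WT with the standard error derived from the edgeR fit. Poisson intervals at 95% cover counting error only, since reads without molecular identifiers are not independent molecules.

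Before the data were examined, 42 gene lists (1036 genes, of which 1030 have a symbol in the tables) were fixed for cell types and pathways of the injured liver, and 38 had at least 5 tested members. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 38 lists. Each list was also tested with a correlation estimated from the data and with fry, for change on balance in one direction and for change in either direction (mixed). The members of each list were counted over all genes tested and adjusted over the list alone. The list mean per library is the mean log2 CPM of its tested members minus the mean of the WT libraries. The members are markers and pathway genes from general knowledge, and markers are shared by several cell types, such as MHC class II genes.

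The genes named in the text were chosen by a rule fixed at the same time: Akap12; up to 12 genes in each direction with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between genotypes, of which there were 0; the 4 members with the smallest edgeR p of each list that is described (which lists are described by their genes was settled after the list results were seen); and 15 genes of fibrosis and its resolution (Col1a1, Col1a2, Col3a1, Acta2, Timp1, Mmp2, Mmp9, Mmp13, Krt7, Krt19, Lrat, Lyve1, Thy1, Fbln2 and Cd34). Genes within 5 Mb of Akap12 were to be named if they passed the test, and 0 did. Other genes are named as chosen after their values were seen.

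Positions are from the RefSeq genes of GRCm38.p6, the assembly that mm10 represents, and the Akap12 transcripts from GENCODE on the same assembly. Of the 12220 tested symbols 12186 had a position, 11700 by their symbol and 486 by a synonym. Genes within 20 Mb of Akap12 were compared with all others by a one-sided Fisher's exact test (scipy 1.17.1), with windows of 5 and 40 Mb and an unadjusted p under 0.01 as alternatives.

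The alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, RLE and upper-quartile factors, library sizes alone, no filter on low counts, a filter of 1 CPM in 3 libraries, dispersions without robust estimation, an adjusted p under 0.1, an absolute log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. The 10 splits of the 6 libraries into groups of 3 were refitted in the same way.

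The tests were tried on simulated counts for AKAP12KO against WT with 200 changed genes, 50 at each of 4 fold sizes, among 12067 genes tested. The edgeR test recovered 28% of genes changed 1.5-fold, 76% of those changed 2-fold, 96% at 4-fold and 100% at 8-fold, and 19 of its 169 calls were genes simulated as unchanged. In a simulation over 12056 genes with the cholangiocyte list shifted by 0.8 on the log2 scale, camera recovered it with the preset correlation (adjusted p = 3.67e-19) and with an estimated correlation (adjusted p = 0.0192), and called 0 of 35 unchanged lists with either, where simulated genes varied independently of each other. Figures were drawn with matplotlib.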

Results

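Liver RNA was sequenced from 6 adult C57BL/6 mice, of which 3 were labelled wild type (WT) and 3 AKAP12 knockout (AKAP12KO). AKAP12, also called gravin, is a scaffold protein that anchors protein kinase A and protein kinase C. All 6 mice had received chow with 0.1% DDC for 3 weeks and then returned to a normal diet for 2 weeks before the liver was taken. DDC (a diethoxycarbonyl dihydrocollidine) blocks heme synthesis and plugs bile ducts with porphyrin. It causes ductular proliferation and fibrosis around the portal tracts, which regress once the diet is withdrawn. The libraries held between 11680792 counts (WT 3) and 13134603 counts (WT 2) assigned to genes. Between 14006 (AKAP12KO 2) and 15482 (AKAP12KO 3) of 24421 gene symbols had at least 1 count. The 20 most abundant genes took from 23.0% to 24.2% of the counts. The Y-linked transcript Eif2s3y was present in every library, from 50.2 to 74.6 in counts normalised to library size (CPM), and Xist did not exceed 0.236 CPM in any. AKAP12KO 2 stood apart from the rest. It lay at 47.0 on the first principal component, which held 36.9% of the variance, with the other 5 libraries between -15.3 and -0.95. Its mean correlation with the others was 0.967 against 0.977 to 0.980 for the rest.

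Akap12 itself (chromosome 10, 4266329 to 4359471, plus strand, GRCm38; 3 annotated transcripts in GENCODE) was weakly expressed and did not separate the genotypes. The WT libraries held 33, 15 and 27 Akap12 counts and the AKAP12KO libraries 18, 7 and 10. These counts correspond to 2.12 ± 0.87 CPM in WT and 0.906 ± 0.459 CPM in AKAP12KO (SD, n = 3 each), so that the mean in AKAP12KO was 42.6% of that in WT. The log2 fold change was -1.22 ± 0.48 (SE; edgeR quasi-likelihood adjusted p = 0.698). A two-sided exact permutation test of the CPM values gave p = 0.2, where 0.1 is the smallest value that 3 mice against 3 allow. AKAP12KO 1, at 1.42 CPM (95% Poisson interval 0.844 to 2.25, counting error only), lay above WT 2, at 1.18 CPM (0.662 to 1.95). Counts were given per whole gene, so reads from exons outside a deletion count in full, and Akap12 does not check the labels here. AKAP12KO below therefore means the libraries labelled as such.

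The comparison of the labelled genotypes asks how the liver transcriptome after withdrawal of DDC depends on AKAP12. All 6 libraries come from this 1 stage. A difference that was present before or during the DDC diet therefore cannot be told apart from one that arose after it. Genes of bile duct epithelium, collagens, other matrix proteins and macrophages rose as groups in the libraries labelled AKAP12KO by a test with a preset correlation between genes. These calls were lost when the correlation was estimated: adjusted p = 0.383 with an estimated correlation for the cholangiocyte and monocyte lists, 0.392 for matrix glycoproteins, 0.399 for collagens and 0.459 for resident macrophages. The median fold change was 0.78 on the log2 scale for 20 cholangiocyte markers, 0.43 for 20 monocyte-derived macrophage markers and 0.34 for 16 collagens. Chaperones of the endoplasmic reticulum fell as a group, with a median log2 fold change of -0.20 over 34 genes (adjusted p = 0.411 with an estimated correlation). Markers of the sinusoidal endothelium, the other large nonparenchymal compartment, had a median of 0.01 over 19 genes and did not pass the test. No single gene passed the threshold over all genes tested with edgeR.

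Of 12220 genes tested, 0 were higher and 0 lower in AKAP12KO at an adjusted p under 0.05 with edgeR's quasi-likelihood test, and the smallest adjusted p was 0.687. At an unadjusted p under 0.05, 421 genes were higher and 433 lower, 854 in all where chance gives 611. DESeq2 called 1 gene higher and 4 lower, and limma-voom called 0 in either direction with and without sample quality weights. The 3 AKAP12KO values lay entirely above or below the 3 WT values in 1582 genes, or 12.9%, against 10% by chance. A split that mixed the genotypes, WT 1, WT 3 and AKAP12KO 3 against the others, gave more, 1700 genes or 13.9%. The spread between mice of a genotype corresponded to a biological coefficient of variation of 17.4%, and the median 95% interval of a log2 fold change reached 0.39 to either side. Of 38 gene lists with enough tested members, 13 were higher and 5 lower in AKAP12KO by limma's camera test with a preset correlation between genes. With an estimated correlation 0 of the 38 lists passed (camera, smallest adjusted p = 0.383 with an estimated correlation), and 4 lists had an unadjusted p under 0.05: the cholangiocyte, monocyte, matrix protease and matrix glycoprotein lists. The fry test of direction called 1 list, the inflammatory genes. The mixed fry test, of change in either direction, called 5 lists, those of protease inhibitors (mixed fry adjusted p = 0.00451) and of vascular endothelial (0.000847), cholangiocyte (0.00267), monocyte (0.0197) and collagen genes (0.0285). Neither fry test compares a list with other genes, and a mixed call gives no direction.

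**Figure D1:**
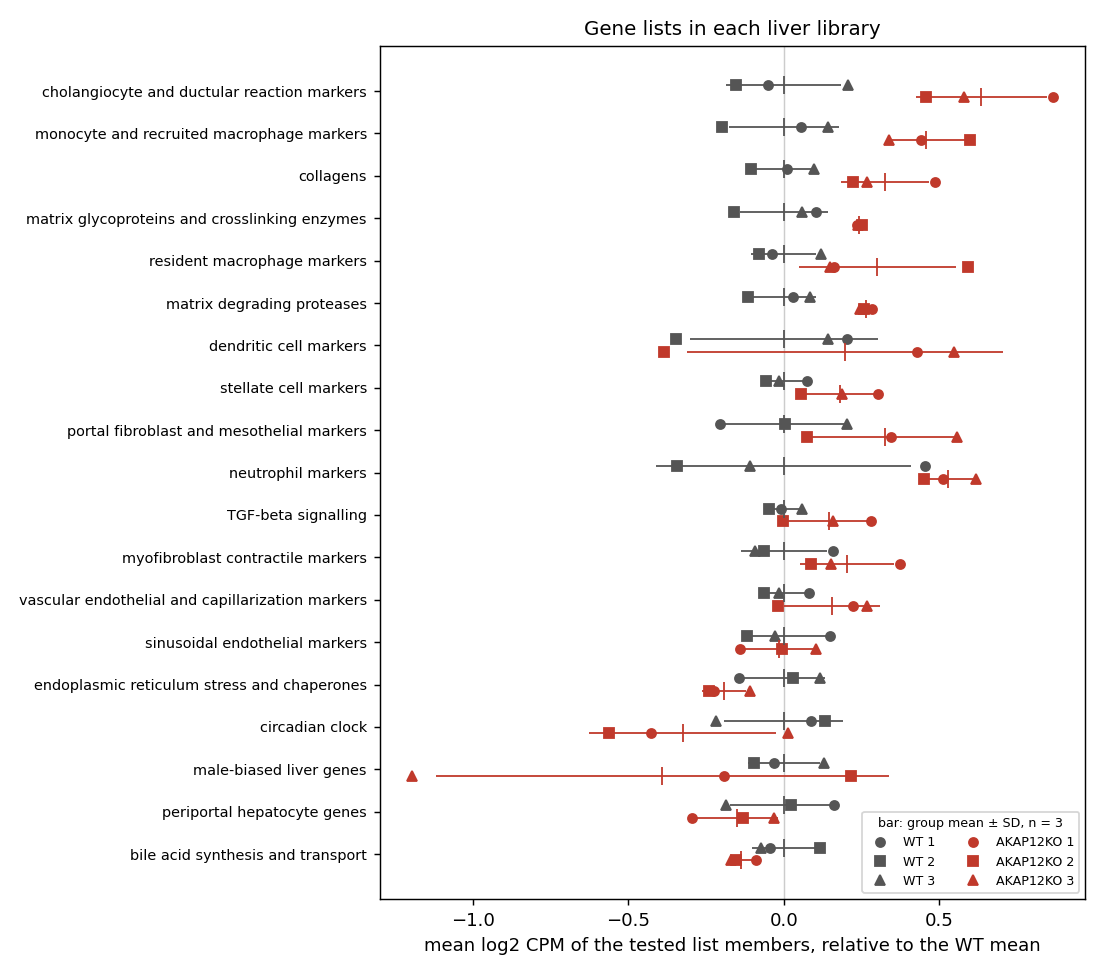
Mean log2 CPM of the tested members of each gene list in each liver library, relative to the WT mean (x axis), for the 18 lists that passed the preset-correlation test and for the sinusoidal endothelial markers (y axis). Grey symbols are the 3 WT and red symbols the 3 AKAP12KO libraries, with the group mean ± SD as a bar; all AKAP12KO libraries lie above all WT libraries for the cholangiocyte, monocyte, collagen, matrix glycoprotein, resident macrophage and matrix protease lists, whereas AKAP12KO 3 alone lies at -1.20 for the male-biased genes.

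Markers of cholangiocytes and of the ductular reaction, the expansion of bile duct cells that DDC provokes, rose in AKAP12KO (camera adjusted p = 1.77e-08; adjusted p = 0.383 with an estimated correlation). Of 20 tested members 16 had a positive and 4 a negative log2 fold change; 2 were higher when adjusted over the list alone, and 0 over all genes tested. Epcam, an adhesion molecule of biliary epithelium, measured 0.997 ± 0.259 CPM in WT and 3.53 ± 0.34 CPM in AKAP12KO, a log2 fold change of 1.81 ± 0.34 (SE). Cd24a, a surface glycoprotein of biliary progenitors, measured 3.18 ± 0.70 and 6.04 ± 0.89 CPM. The tight junction gene Cldn7 had a log2 fold change of 1.76 ± 0.62 and the sodium-glucose transporter gene Slc5a1 one of 1.38 ± 0.49. Both rest on low counts, at 0.427 ± 0.236 and 1.45 ± 0.86 CPM for Cldn7 and 0.693 ± 0.223 and 1.82 ± 0.76 CPM for Slc5a1. The biliary keratins Krt7 and Krt19 measured 1.18 ± 0.25 and 1.22 ± 0.31 CPM in WT against 2.28 ± 0.70 and 2.20 ± 0.90 CPM in AKAP12KO. The genotypes parted only narrowly in both. Krt7 held at most 17 counts in a WT and at least 20 in an AKAP12KO library, and Krt19 at most 20 and at least 22. Their log2 fold changes were 0.95 ± 0.39 and 0.84 ± 0.41 (Krt19 at 0.47 without AKAP12KO 1). The list mean lay between -0.15 and 0.20 in the WT libraries and between 0.46 and 0.87 in the AKAP12KO libraries, on the log2 scale relative to the WT mean.

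Collagens rose in AKAP12KO (camera adjusted p = 4.78e-06; adjusted p = 0.399 with an estimated correlation), with 15 of 16 tested members above 0. Adjusted over the list alone, 4 collagens were higher, and 0 over all genes tested. Col1a1 and Col1a2, the chains of type I collagen that forms scar fibres, measured 14.95 ± 2.73 and 22.8 ± 2.6 CPM in WT and 22.0 ± 1.7 and 34.1 ± 2.4 CPM in AKAP12KO. Their log2 fold changes were 0.56 ± 0.16 and 0.58 ± 0.13. Col6a3, of microfibrillar type VI collagen, and Col4a2, of basement membrane, had log2 fold changes of 0.62 ± 0.18 and 0.57 ± 0.17. Col3a1, the chain of type III collagen, measured 65.3 ± 10.6 and 80.2 ± 7.4 CPM (0.30 ± 0.14 on the log2 scale) with overlapping genotypes.

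Matrix glycoproteins and collagen crosslinking enzymes also rose (22 of 28 members above 0; camera adjusted p = 4.98e-05; adjusted p = 0.392 with an estimated correlation). Adjusted over the list alone 0 members passed, as over all genes tested by edgeR, and 3 had an unadjusted p under 0.05. The proteoglycan gene Bgn had a log2 fold change of 0.47 ± 0.14, the collagen chaperone gene Serpinh1 one of 0.47 ± 0.14. The lysyl oxidase genes Loxl1 and Loxl3, whose products crosslink collagen and elastin, gave 0.67 ± 0.27 and 0.67 ± 0.32. Proteases that degrade matrix rose as well (14 of 17 members above 0; median 0.34; camera adjusted p = 0.00364; adjusted p = 0.383 with an estimated correlation). By edgeR 0 of them passed adjusted over the list alone or over all genes tested, and 4 had an unadjusted p under 0.05. Their leading members were Mmp12, the macrophage elastase (9.96 ± 1.49 and 17.2 ± 7.1 CPM), Mmp23 (log2 fold change 0.95 ± 0.36), the plasminogen activator gene Plat (1.03 ± 0.41) and the cathepsin gene Ctss (0.30 ± 0.13). Mmp12 overlapped between genotypes, and without AKAP12KO 2 the log2 fold change of Mmp12 was 0.42, against 0.79 with all libraries, and that of Plat 0.54. Mmp2, the stellate cell gelatinase, measured 7.34 ± 0.93 and 9.74 ± 1.02 CPM. The transcripts Mmp9 (0.701 ± 0.207 and 0.624 ± 0.366 CPM) and Mmp13 (0.541 ± 0.353 and 0.768 ± 0.251 CPM) lay below the expression filter and were not tested. The protease inhibitors of matrix turnover did not pass as a list (6 of 9 members above 0; camera adjusted p = 0.115; 0.0313 without AKAP12KO 2). Among them Spint1, an epithelial inhibitor of hepatocyte growth factor activator, was higher adjusted over the list alone (0.277 ± 0.089 and 1.08 ± 0.09 CPM) and not over all genes tested. Timp1, the fibrosis-associated metalloproteinase inhibitor, measured 0.985 ± 0.249 and 0.846 ± 0.205 CPM, at a log2 fold change of -0.21 ± 0.46. Timp2, Timp3 and Cst3 had log2 fold changes of 0.25 ± 0.18, 0.39 ± 0.19 and 0.14 ± 0.13.

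Markers of hepatic stellate cells, the vitamin A-storing pericytes that give rise to myofibroblasts, rose by a median of 0.17 (14 of 18 members above 0; camera adjusted p = 0.00826; adjusted p = 0.411 with an estimated correlation). The call was lost without AKAP12KO 1 (camera adjusted p = 0.0822). Pdgfrb, the receptor of the stellate cell mitogen PDGF-B, was the single member higher adjusted over the list alone (13.2 ± 1.2 and 20.7 ± 3.4 CPM). Over all genes tested by edgeR 0 members passed, with 3 members higher and 1 lower at an unadjusted p under 0.05. Hand2 and the decoy TGF-beta receptor gene Bambi had log2 fold changes of 0.61 ± 0.25 and 0.49 ± 0.22, and Colec10 one of -0.50 ± 0.22. Lrat, which esterifies retinol in quiescent stellate cells, measured 13.3 ± 1.8 and 14.5 ± 1.0 CPM. Contractile genes of myofibroblasts rose by a median of 0.22 (11 of 13 above 0; camera adjusted p = 0.0268; adjusted p = 0.459 with an estimated correlation). The actin crosslinker gene Flna (17.0 ± 3.0 and 26.0 ± 3.1 CPM) was the 1 member higher adjusted over the list alone, with 0 over all genes tested. Vim, Des and Cald1 had log2 fold changes of 0.34 ± 0.15, 0.63 ± 0.30 and -0.22 ± 0.12. The call was lost without WT 2 (camera adjusted p = 0.0602) and without AKAP12KO 1 (0.181). Acta2, the smooth muscle actin of activated myofibroblasts, measured 1.10 ± 0.76 and 1.46 ± 1.07 CPM, and its log2 fold change of 0.40 ± 0.62 turned to -0.36 without AKAP12KO 1. Markers of portal fibroblasts and mesothelium rose by a median of 0.30 (10 of 12 above 0; camera adjusted p = 0.00845; adjusted p = 0.411 with an estimated correlation). That call was lost without WT 1 (camera adjusted p = 0.157) and without AKAP12KO 3 (0.131). Among them elastin, Eln, was higher adjusted over the list alone (3.33 ± 0.55 and 7.39 ± 2.56 CPM; log2 fold change 1.15 ± 0.29), with 0 members over all genes tested. The elastic fibre gene Mfap4 had a log2 fold change of 0.95 ± 0.34, the PDGF receptor gene Pdgfra 0.83 ± 0.28 and the mesothelial gene Gpm6a -0.52 ± 0.30. Other portal fibroblast markers gave 0.44 ± 0.41 (Thy1), 0.30 ± 0.34 (Cd34) and 0.31 ± 0.38 (Fbln2, at -0.01 without AKAP12KO 3). Cd34 measured 3.72, 2.04 and 4.91 CPM in AKAP12KO 1, 2 and 3, against 2.64 to 3.15 CPM in WT. Thy1 was lowest in WT 1, at 0.701 CPM, with 1.42 and 1.62 CPM in WT 2 and WT 3 and 1.58 to 1.81 CPM in AKAP12KO. Genes of TGF-beta signalling, the main fibrogenic pathway, rose by a median of 0.22 (24 of 34 above 0; camera adjusted p = 0.0157; adjusted p = 0.411 with an estimated correlation). By edgeR 0 members passed adjusted over the list alone or over all genes tested, and 3 had an unadjusted p under 0.05. The inhibitory Smad gene Smad6 and the matricellular gene Ctgf had log2 fold changes of 0.78 ± 0.31 and 0.63 ± 0.29. Ctgf reached 8.04 CPM in AKAP12KO 3, with 5.69 and 4.32 CPM in the other AKAP12KO libraries and 2.99 to 4.90 CPM in WT. The call of the TGF-beta list was lost without AKAP12KO 1 (camera adjusted p = 0.098) and without AKAP12KO 3 (0.105).

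Myeloid markers rose in AKAP12KO. Of 20 markers of monocytes and recruited macrophages 18 were above 0 (camera adjusted p = 3.66e-07; adjusted p = 0.383 with an estimated correlation). In edgeR 0 passed adjusted over the list alone or over all genes tested, and 8 had an unadjusted p under 0.05. Lyz2, the myeloid lysozyme, measured 80.8 ± 8.3 and 114 ± 21 CPM. The lipid-associated macrophage genes Trem2, Gpnmb and Lgals3 had log2 fold changes of 0.87 ± 0.24, 1.06 ± 0.31 and 1.04 ± 0.33. Gpnmb reached 64.3 CPM in AKAP12KO 2 and 28.9 and 29.6 CPM in the other AKAP12KO libraries, against 18.3 to 20.3 CPM in WT. Lgals3 likewise reached 31.3 CPM in AKAP12KO 2, with 15.8 and 13.1 CPM in the others and at most 12.2 CPM in WT. Without AKAP12KO 2 the log2 fold changes of Gpnmb and Lgals3 were 0.58 and 0.57. Markers of resident macrophages, the Kupffer cells, rose by a median of 0.31 (14 of 16 above 0; camera adjusted p = 0.000571; adjusted p = 0.459 with an estimated correlation). Here 2 members were higher adjusted over the list alone and 0 over all genes tested. They were the complement gene C1qc (38.4 ± 2.6 and 57.7 ± 14.3 CPM) and the macrophage growth factor receptor gene Csf1r (28.6 ± 2.9 and 39.8 ± 5.6 CPM). The Kupffer cell lectin gene Clec4f and the scavenger receptor gene Marco had log2 fold changes of 0.41 ± 0.14 and 0.65 ± 0.24. The resident macrophage list mean was 0.59 in AKAP12KO 2 and 0.15 and 0.16 in the other AKAP12KO libraries. Dendritic cell markers rose by a median of 0.42 (9 of 11 above 0; camera adjusted p = 0.00552; adjusted p = 0.471 with an estimated correlation). They were led by genes of antigen presentation by MHC class II, which macrophages and B cells also express. Of these, Cd74 (73.6 ± 4.1 and 110 ± 16 CPM) and H2-Eb1 (26.3 ± 3.3 and 39.3 ± 9.7 CPM) were higher adjusted over the list alone, 2 in all, and 0 passed over all genes tested. The dendritic list mean was -0.39 in AKAP12KO 2 and 0.43 and 0.55 in the others. The call was lost without WT 2 (camera adjusted p = 0.0791) and without AKAP12KO 3 (0.117). Neutrophil markers rose by a median of 0.43 over only 5 tested members (4 above 0; camera adjusted p = 0.0152; adjusted p = 0.411 with an estimated correlation). The granule gene Ngp was higher adjusted over the list alone, at 0.341 ± 0.184 and 1.16 ± 0.27 CPM, and 0 members over all genes tested. S100a9, Csf3r and Hdc had log2 fold changes of 0.43 ± 0.32, 0.81 ± 0.33 and -0.33 ± 0.32. That call was lost without WT 2 (camera adjusted p = 0.0602) and without AKAP12KO 3 (0.11).

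Lymphocyte lists did not pass. T and NK cell markers had 8 of 12 members above 0 (camera adjusted p = 0.0756; 0.0256 without WT 1, 0.0485 without AKAP12KO 1 and 0.0256 with the filter of 1 CPM). Their log2 fold changes were 0.89 ± 0.40 for Lck, 0.75 ± 0.36 for Klrk1, 0.67 ± 0.41 for Il2rb and -1.11 ± 0.45 for the granzyme gene Gzma. B and plasma cell markers had 5 of 8 above 0 (camera adjusted p = 0.53). The inflammatory cytokines and NF-kB targets had 17 of 21 members above 0 at a median of 0.12. They passed fry's test of direction (fry adjusted p = 0.0302) but not camera, which compares them with other genes (camera adjusted p = 0.126). Relb, Tlr4, Vcam1 and Il18 had log2 fold changes of 0.72 ± 0.31, 0.75 ± 0.46, 0.30 ± 0.19 and -0.22 ± 0.15. Tlr4 reached 2.43 CPM in AKAP12KO 2, with 1.27 and 0.967 CPM in the other AKAP12KO libraries and 0.876 to 0.946 CPM in WT.

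Sinusoidal endothelial markers had 10 of 19 members above 0 (median 0.01, mean -0.01; camera adjusted p = 0.977). Stab1, Stab2, Fcgr2b and Maf had log2 fold changes of 0.27 ± 0.19, 0.17 ± 0.13, -0.21 ± 0.15 and -0.53 ± 0.30. The hyaluronan receptor gene Lyve1 measured 5.43 ± 0.29 and 5.27 ± 0.65 CPM, and its log2 fold change of -0.04 ± 0.22 took the opposite sign with library sizes alone (0.034). Markers of vascular endothelium and of capillarization rose by a median of 0.22 (11 of 17 above 0; camera adjusted p = 0.0296; adjusted p = 0.459 with an estimated correlation). The von Willebrand factor gene Vwf (2.21 ± 0.55 and 4.43 ± 0.43 CPM) led this list. By edgeR 0 members passed adjusted over the list alone or over all genes tested, and 3 had an unadjusted p under 0.05. Sox17, Eng and Plvap had log2 fold changes of 0.74 ± 0.30, 0.40 ± 0.16 and 0.28 ± 0.14. Eng reached 66.7 CPM in AKAP12KO 1, with 45.0 and 48.4 CPM in the other AKAP12KO libraries and 34.7 to 43.5 CPM in WT. The call was lost without WT 2 (camera adjusted p = 0.139), without AKAP12KO 3 (0.211) and with no filter on low counts (0.113). The vascular minus the sinusoidal list mean was 0.17 ± 0.19 higher in AKAP12KO than in WT (SD of the 3 AKAP12KO libraries), and the genotypes overlapped.

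**Figure D2:**
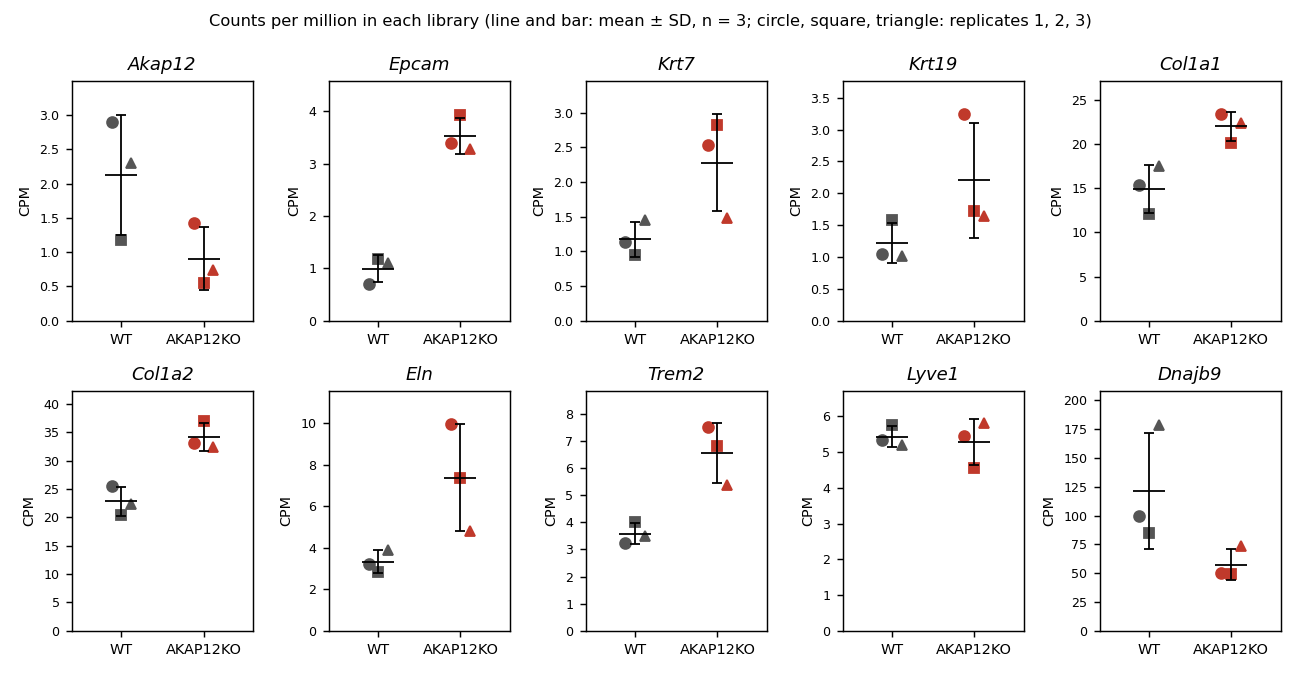
Normalised counts (CPM; y axes, linear from 0) of 10 genes in each library, with WT in grey and AKAP12KO in red; circles, squares and triangles are replicates 1, 2 and 3, and lines with bars are the mean ± SD (n = 3). Epcam, Krt7, Krt19, Col1a1, Col1a2, Eln and Trem2 lie higher in every AKAP12KO library than in any WT library and Dnajb9 lower, while Akap12 and Lyve1 overlap. The genotypes part only narrowly for Krt7 and Krt19.

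The 5 lists that fell in AKAP12KO held genes of protein folding, the circadian clock and hepatocyte metabolism, and their shifts were small. Chaperones and genes of the endoplasmic reticulum stress response fell (29 of 34 members below 0; camera adjusted p = 0.000579; adjusted p = 0.411 with an estimated correlation). In edgeR 0 members passed adjusted over the list alone or over all genes tested, and 6 had an unadjusted p under 0.05. The co-chaperone gene Dnajb9 measured 121 ± 50 CPM in WT and 57.5 ± 13.9 CPM in AKAP12KO (log2 fold change -1.08 ± 0.31). The degradation factor gene Herpud1, Sdf2l1 and Dnajc3 had log2 fold changes of -0.41 ± 0.15, -0.39 ± 0.14 and -0.28 ± 0.10. Clock genes fell, at a median log2 fold change of -0.21 (17 of 21 below 0; camera adjusted p = 0.00364; adjusted p = 0.459 with an estimated correlation). Their call was lost without AKAP12KO 2 (camera adjusted p = 0.0534). The repressor gene Bhlhe40 (236 ± 20 and 165 ± 20 CPM) was the single member lower adjusted over the list alone, with 0 over all genes tested. Bhlhe41, Ciart and Per1 had log2 fold changes of -0.95 ± 0.31, -0.94 ± 0.44 and -0.65 ± 0.33. Periportal hepatocyte genes fell, at a median of -0.13 (19 of 24 below 0; camera adjusted p = 0.0109; adjusted p = 0.525 with an estimated correlation). Of these 0 passed adjusted over the list alone or over all genes tested by edgeR, and 3 had an unadjusted p under 0.05. Tdo2, of tryptophan breakdown, measured 1461 ± 125 and 1086 ± 138 CPM and Pck1, of gluconeogenesis, 1927 ± 334 and 1288 ± 353 CPM. Sds and Etnppl had log2 fold changes of -0.35 ± 0.15 and -0.52 ± 0.23. That call was lost without WT 1 (camera adjusted p = 0.184), WT 2 (0.0791) or AKAP12KO 1 (0.132). Genes of bile acid synthesis and transport fell, at a median of -0.08 (22 of 29 below 0; camera adjusted p = 0.0453; adjusted p = 0.411 with an estimated correlation). The call was lost without WT 2 (camera adjusted p = 0.296) and without AKAP12KO 3 (0.177). In this list the uptake transporter gene Slco1a1 (474 ± 37 and 323 ± 33 CPM) was lower adjusted over the list alone, 1 member, with 0 over all genes tested. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, Slco1b2 and the apical bile acid transporter gene Slc10a2 had log2 fold changes of -0.50 ± 0.20, -0.35 ± 0.14 and -0.38 ± 0.20. Genes expressed more in male than in female liver fell, at a median of -0.27 (17 of 21 below 0; camera adjusted p = 0.00411; adjusted p = 0.615 with an estimated correlation). Their list mean was -1.20 in AKAP12KO 3 and -0.19 and 0.22 in the other AKAP12KO libraries, and without AKAP12KO 3 the camera adjusted p was 0.955 with the opposite sign. Slco1a1 belongs to this list too and was its only member lower adjusted over the list alone, with 0 over all genes tested. Mup21, Ugt2b1 and Cyp4a12a had log2 fold changes of -0.77 ± 0.31, -0.45 ± 0.25 and -0.31 ± 0.19.

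The remaining lists did not pass with all 6 libraries. Heme synthesis and breakdown, the pathway that DDC disturbs, had 7 of 19 members above 0 (camera adjusted p = 0.806). Hmox1, the inducible heme oxygenase, was its single member higher adjusted over the list alone (15.02 ± 1.03 and 21.9 ± 1.5 CPM; log2 fold change 0.54 ± 0.14) and not over all genes tested. Fech, the ferrochelatase that DDC products inhibit, Ppox and Abcg2 had log2 fold changes of -0.12 ± 0.12, 0.21 ± 0.14 and -0.17 ± 0.13. The camera adjusted p was 0.0574 for oxidative phosphorylation, 0.0929 for cytosolic ribosomal proteins, 0.0959 for the cell cycle, 0.127 for cholesterol synthesis, 0.168 for xenobiotic metabolism, 0.178 for gluconeogenesis and cAMP signalling and 0.273 for pericentral hepatocyte genes. It was 0.507 for acute phase proteins, 0.53 for Nrf2 targets, 0.606 for lipogenesis, 0.709 for adipocyte genes, 0.731 for fatty acid oxidation, 0.895 for the interferon response and 0.987 for female-biased genes. Several of these lists passed once 1 library was left out. Lower lists of that kind were oxidative phosphorylation without WT 3 (camera adjusted p = 0.000212) or AKAP12KO 2 (0.0355), and cholesterol synthesis without WT 1 (0.0133), AKAP12KO 1 (0.00434) or AKAP12KO 3 (0.0139). Xenobiotic metabolism was lower without WT 3 (0.0201) or AKAP12KO 3 (0.00326), and the female-biased genes, whose test had a positive sign with all libraries, were lower without AKAP12KO 3 (0.0139). Higher lists were the ribosomal proteins without WT 2 (0.00596) or AKAP12KO 3 (0.0139) and the cell cycle without WT 3 (0.0256), AKAP12KO 1 (0.0485) or AKAP12KO 3 (0.0139). Lipogenesis was higher without AKAP12KO 2 (0.00173) and fatty acid oxidation without WT 2 (0.0482). Other settings also brought calls for ribosomal proteins (0.02 with library sizes alone, 0.0454 with upper-quartile factors), cholesterol synthesis (0.0435 with library sizes alone), and, with no filter on low counts, oxidative phosphorylation (0.0294) and the cell cycle (0.0397). The median was slightly negative and the test positive in sign for fatty acid oxidation (-0.01) and the interferon response (-0.02). The mean was negative and the test positive for the sinusoidal markers. For the female-biased genes the fitted median was 0.56 while the group mean of log2 CPM was -0.24. Erythrocyte, pancreatic acinar, skeletal muscle and sex chromosome genes had 2, 1, 2 and 4 tested members and were too few for a test. Alas2, an erythroid heme synthesis gene, was lower adjusted over the list alone and not over all genes tested by edgeR. The 10 globin gene symbols of the tables were listed at 0 in every library.

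Genes linked to Akap12 were compared with the rest of the genome, since flanking sequence of the targeted embryonic stem cells can stay with a targeted allele. Within 20 Mb of Akap12 on chromosome 10, 0 of 67 tested genes and elsewhere 0 of 12118 passed edgeR's adjusted threshold, so no Fisher test was possible. At an unadjusted p under 0.01 there were 2 of 67 near and 163 of 12118 far genes (one-sided Fisher's exact test, p = 0.23). These genes, named after their values were seen, were Mthfd1l (chromosome 10, 3972892 to 4167081; log2 fold change 1.42 ± 0.41; 2.47 ± 0.35 and 6.61 ± 3.91 CPM), a mitochondrial folate enzyme gene, and Adgb (chromosome 10, 10335703 to 10475093; -2.63 ± 0.71; 1.49 ± 0.55 and 0.233 ± 0.237 CPM). Their edgeR adjusted p values were 0.688 and 0.687.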

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

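All settings here were planned. With DESeq2, which tested 16933 genes, 1 gene was higher and 4 were lower, against 0 and 0 with edgeR, and leaving out each library in turn gave from 0 to 1 genes higher and from 0 to 1 lower. Without WT 3 the lower gene was Upp2, and without AKAP12KO 3 Apoa4 was higher and Thrsp lower. The number of gene lists changed, 18 with the preset correlation, was 0 with an estimated correlation, 1 with the fry test of direction and 5 with mixed fry. For camera the size of the correlation alone does not account for this. As given below, estimating it also weakened camera for simulated genes that varied independently. A lost call therefore does not show that a list is unchanged. With the preset correlation the number lay between 14 and 21 without each library in turn and between 18 and 20 under the other scalings and filters. Of the 13 higher lists 6 were called in each of the 6 fits that left out a library, and of the 5 lower lists 1. Genes near Akap12 on its chromosome numbered 0 at the adjusted threshold with windows of 5, 20 and 40 Mb and, at the looser threshold of an unadjusted p under 0.01, 2 within 20 Mb, 1 within 5 Mb and 3 within 40 Mb.

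Of 100 named genes tested, 97 never changed sign over all alternatives. Most of them were picked for a small p in these same libraries, so a stable sign was likely in advance. Leaving out each library in turn took the log2 fold change of Acta2 from -0.36 (without AKAP12KO 1) to 1.06 and that of Fbln2 from -0.011 (without AKAP12KO 3) to 0.54. That of Lyve1 was 0.034 with library sizes alone and ran from -0.099 to 0.051 (positive without AKAP12KO 2, and without WT 2 at 0.0088). Dnajb9 passed with DESeq2 alone (adjusted p = 0.0302). The cause was not tested in these genes. Akap12 stayed between -1.68 and -0.94 and did not pass in any setting. At an unadjusted p under 0.05, genes higher in AKAP12KO and genes lower in AKAP12KO numbered 421 and 433 with TMM factors, 736 and 152 with library sizes alone, and 567 and 286 with upper-quartile factors, where the median log2 fold change of all genes moved by 0.07 and 0.04. Same-numbered WT and AKAP12KO libraries deviated with correlations of -0.17, -0.06 and -0.10. These values show no pairing of the mice by number, but so few cannot exclude it. With the replicate number as a block 0 genes passed in either direction and 18 lists did, of which 17 were among the 18 above. Bile acid synthesis and transport no longer passed (camera adjusted p = 0.0687), and cholesterol synthesis did (0.0497). Low counts limit Akap12, Krt7, Krt19, Acta2, Timp1, Mmp9 and Mmp13, all near 1 or 2 CPM or below. Spint1, Ngp, Cldn7 and Slc5a1 are limited as well, at 0.277, 0.341, 0.427 and 0.693 CPM in WT, and so is Epcam at 0.997 CPM. Other named genes near 1 CPM, such as Lck, Klrk1 and Tlr4, share this limit.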

Other observations

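In this part the DESeq2 test, the fits that leave out a library and the splits of the libraries were planned, and the other tests were chosen after the results were seen. DESeq2 called 5 genes that edgeR did not, named after their values were seen. Apoa4, a lipoprotein gene of intestine and fasted liver, measured 133 ± 6 CPM in WT and 264 ± 67 CPM in AKAP12KO (DESeq2 adjusted p = 0.000283; edgeR adjusted p = 0.687). Upp2, a uridine phosphorylase gene, measured 344 ± 132 and 141 ± 16 CPM (DESeq2 adjusted p = 0.000283), Arhgef26 53.4 ± 19.5 and 23.7 ± 3.4 CPM (0.00477), Dnajb9 121 ± 50 and 57.5 ± 13.9 CPM (0.0302), and the aldo-keto reductase gene Akr1c14 527 ± 74 and 343 ± 29 CPM (0.0313). The values of all 5 genes did not overlap between the genotypes.

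Single AKAP12KO libraries differed strongly in other programmes. The cell cycle list mean was 0.69 in AKAP12KO 2, against 0.04 and 0.16 in the other AKAP12KO libraries and -0.08 to 0.15 in WT, and its cholesterol synthesis mean was -0.83 against 0.17 in both others. The proliferation marker Mki67 reached 9.81 CPM and the female-biased gene Cyp2c40 30.8 CPM there. The female-biased list as a whole was not high in AKAP12KO 2. Its mean was -0.39, and its members Cyp2b9 and Cyp2a4 measured 1.65 and 2.20 CPM. Some unrelated genes were absent from AKAP12KO 2. Ldhb measured 0 CPM there against 1.23 to 2.83 CPM in the other libraries, and Plxna3 0 against 1.03 to 1.49 CPM. Both were among the genes with the most negative loadings on the first principal component. Whether the mouse or the library preparation differed was not tested. In AKAP12KO 3 genes of the male liver programme were low: Mup7 measured 326 CPM against 2463 to 5017 CPM in the other 5 libraries, Selenbp2 92.1 against 551 to 1413 CPM and Hsd3b5 71.4 against 249 to 369 CPM. The female-biased genes Cyp2b9 and Cyp2a4 measured 34.5 and 44.3 CPM there, against at most 11.2 and 12.5 CPM in the other libraries, but Cyp2c40 and Cyp2c69, of the same list, were both at 0.298 CPM, the lowest of the 6 libraries. Xist stayed at 0.149 CPM in AKAP12KO 3, and the 4 Y-linked genes averaged 28.8 CPM, within the 24.1 to 40.7 CPM of the other libraries. Alas2 measured 112 to 159 CPM in the 6 libraries while the 10 globin symbols were listed at 0.

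The rise of 13 lists of ductular, matrix, mesenchymal, myeloid and vascular endothelial genes was called only by camera with the preset correlation. With an estimated correlation 0 of the 13 passed (smallest adjusted p = 0.383 with an estimated correlation), and the fry test of direction called none of them. The size of the correlation alone does not account for this loss. For the matrix proteases the estimated correlation was 0.015, near the preset 0.01 and the lowest of the 13. Other lists lay well above the preset value. The estimate was 0.091 for the cholangiocyte, 0.096 for the monocyte, 0.20 for the collagen and 0.33 for the resident macrophage list. For the matrix proteases the unadjusted camera p was 0.000673 with the preset correlation and 0.0302 with the estimated one. In the simulation with independent genes the camera adjusted p likewise went from 3.67e-19 to 0.0192. Estimating the correlation thus weakened the test even where list members varied independently, so a lost call does not show that a list is unchanged. Mixed fry called 4 of the 13, which shows a change of members in either direction and not a rise. With the preset correlation AKAP12KO 2 alone does not account for the calls, since without that library 13 of the 13 lists were still called higher. A lower share of hepatocytes would raise the markers of every other cell type alike, but the cholangiocyte list mean minus the sinusoidal endothelial list mean was 0.65 higher in AKAP12KO (WT highest 0.23, AKAP12KO lowest 0.46). The gap of 0.230 between these values exceeded the WT SD of 0.217 only narrowly, and the comparison takes the sinusoidal endothelium itself as unchanged. This argues only weakly against a lower share of hepatocytes as the whole cause for the cholangiocyte list, of whose 20 members 1 is in another list. For the other 12 lists it stays open: 6 of the 13 did not overlap between genotypes in this difference, but apart from the cholangiocyte list by less than the WT SD, and the rest, such as the resident macrophage markers (0.32 higher), overlapped. More portal tract in the sampled piece of liver may raise ductular and matrix genes together and stays open too, since the mean of the resident macrophage list, of cells that lie in the sinusoids, was 0.30 higher in AKAP12KO but its lowest AKAP12KO value of 0.15 exceeded the highest WT value of 0.12 by less than the WT SD of 0.10. The labelled genotype also stays open.

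The 3 mice per genotype give only 10 splits, too few for a share under 0.05. The real split gave 18 lists, and the highest other split 20, with 3 splits at 18 or more. The split with 20 lists set WT 1, WT 2 and AKAP12KO 3 against the others. Its smallest unadjusted camera p was that of the circadian clock (2.56e-10). The cholangiocyte, collagen and monocyte lists had an unadjusted camera p of 4.92e-05, 0.000308 and 3.36e-05 there. In the real split these were 4.66e-10, 3.78e-07 and 1.93e-08. The 3 lists were those with the smallest p in the real split, so lower values there follow from how they were picked. The smallest unadjusted camera p of any split was 6.27e-20. It was that of cholesterol synthesis, with WT 1, WT 2 and AKAP12KO 2 set against the others. For genes past the adjusted threshold the real split gave 0 and the highest other 4, so that 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 854 genes and the highest other 1042, with 2 splits as large.

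The Akap12 counts that remained in AKAP12KO, 42.6% of the WT mean, may be reads from exons outside the deletion; per-gene counts cannot decide this. An exchange of WT 2 with AKAP12KO 1 could also bring their Akap12 levels into order, and with both labels exchanged 175 genes had an unadjusted p under 0.05 against 854 as labelled. This does not exclude an exchange, since a genotype of little effect gives few genes either way, so the explanations cannot be told apart.

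The call of clock genes as lower in AKAP12KO was lost without AKAP12KO 2 (camera adjusted p = 0.0534) and with the correlation estimated (adjusted p = 0.459 with an estimated correlation), and the order of the libraries did not follow genotype. The list mean was 0.014 in AKAP12KO 3, -0.43 in AKAP12KO 1 and -0.56 in AKAP12KO 2, against -0.22 to 0.13 in WT. Arntl, which peaks in antiphase to Per genes, measured 1.84 and 2.36 CPM in WT 1 and WT 2 and 1.79 CPM in AKAP12KO 3, against 4.69, 7.04 and 6.04 CPM in WT 3, AKAP12KO 1 and AKAP12KO 2. Per3 measured 43.2, 48.9 and 60.2 CPM in the former and 27.3, 20.5 and 19.3 CPM in the latter. Genotype does not give this order. A candidate explanation is the time of day of tissue collection, but no times are given in the sources used here. Its share in the lower clock list mean of AKAP12KO therefore stays open. Its share in the other called lists stays open too, since the split of the libraries by this order gave the 20 lists above. Bhlhe40, at 150 to 187 CPM in AKAP12KO and 213 to 248 CPM in WT, did not follow that order.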
